A study of Mus musculus with 26 samples.

How the data were processed

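The series profiled mouse cells passing through the endothelial-to-hematopoietic transition, in which arterial endothelial cells (E) become hemogenic endothelium (HE) and then form intra-arterial clusters (IAC) of blood cells. Cells were dissociated from the dorsal aorta together with the umbilical and vitelline arteries at embryonic day 9.5, 10.5 or 11.5, sorted by flow cytometry on the day of harvest and captured in droplets with the Chromium Single Cell 3′ kit, per the labels' protocols. Yolk sac erythro-myeloid progenitors (EMP) of E9.5, lymphoid-primed progenitors (LMPP) of the E11.5 fetal liver and hematopoietic stem cells (HSC) of the E14.5 fetal liver were sorted beside them. The 26 libraries were placed in 20 groups by their labels. A pair of libraries was given for 6 groups (E9.5 E, E9.5 HE, E10.5 E, Runx1+/+ and Runx1+/- at E10.5, and E11.5 IAC), and 1 library for each of the other 14. Nothing in the labels says that the libraries of a group came from separate embryos or litters, so p-values measure the spread between these libraries, which may be technical.

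The deposited matrix held raw UMI counts for 27998 genes in 46048 cells, 696652759 UMIs in all. Per the submitters' processing notes, Cell Ranger and the mouse build mm10 were used, and the Cell Ranger version is not given in the sources used here. The deposited count total of each cell was equal to the sum of its matrix column in 46048 cells. The deposited mitochondrial fraction of each cell was equal to the share of its UMIs from 13 mitochondrial genes. Cells in the matrix had at least 1000 detected genes and at least 1591 UMIs, with a median of 13667. How cells, doublets and ambient RNA were filtered is not given in the sources used here, and no doublet caller was run. The authors' cell annotation placed 34110 cells in 16 types and left 11938 without a type. It gives type names such as Conflux endo and Pre-HE, and adds [AE] or [VE] to some endothelial types without spelling these out. In the authors' annotation 4433 cells were in the type for mesenchymal and other contaminating cells. Each matrix row was kept under its own Ensembl identifier, since 56 symbols were shared by 2 or more identifiers.

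UMI counts were summed over cells, with the library as the replicate. Whole-library comparisons summed all cells of a library and fitted all 26 libraries in one model with a coefficient per group, so that the 6 groups with a pair of libraries gave one shared estimate of the spread with 6 residual degrees of freedom. A group with 1 library was assumed to vary like these. The steps along the transition summed the cells of each annotated type in each E10.5 library with an unselected E+HE+IAC gate and intact Runx1, and also in the CD44+ library. Endo stands here for the authors' types Endo (Wnt_low), Endo (Wnt_high) and Endo (other) pooled, and the order of the types was set for these fits. A type had to have at least 20 cells in a library. Each type was then compared with the one before it, with the library as a term and 13 residual degrees of freedom. The cR1 Cre- library was planned for these fits and could not enter, because none of its cells carries an annotated type. Comparisons of annotated Endo and HE cells by stage, of IAC cells at E11.5 and E10.5, and of the types Endo (Wnt_high) and Endo (Wnt_low) were added after the data were seen. All of these fits left out the Runx1+/- libraries. The first has no library term, although some libraries gave both Endo and HE cells. In all fits on annotated types the types were drawn by the authors from the same expression values. The p-values there describe how evenly a difference runs over libraries, not whether the types exist.

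Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalization, the quasi-likelihood fit without robust weights and its F test), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. These settings, the comparisons other than those added, and the 31 gene lists were fixed before the data were examined. Comparisons with 1 library on each side have no test. Their values are plain CPM, given with exact Poisson intervals that cover counting error only. Shares of cells are given with exact Clopper-Pearson intervals at a confidence level of 95%, which likewise cover counting error only. Shares of the Runx1+/+ and Runx1+/- libraries were compared by an exact two-sided permutation test, whose smallest possible p is 0.333 for 2 libraries against 2. A fold against a side with no UMI is given as a lower bound, computed from UMIs pooled over the libraries of each side with a floor of 3 UMIs on the empty side. Levels in counts-per-million (CPM) are TMM-normalized for the tested comparisons, and plain CPM where only 1 library stands on each side, for values of single types in single libraries and for lower bounds.

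The lists were pan-endothelial, arterial, venous and lymphatic, shear stress response, TGF-beta and BMP response, hemogenic and EHT regulators, RUNX1 targets, pan-hematopoietic, HSC-associated, lymphoid, myeloid, macrophage, erythroid, megakaryocyte, S phase, G2M phase, MYC and ribosome biogenesis, ribosomal proteins, glycolysis, oxidative phosphorylation, cholesterol synthesis, inflammatory and interferon response, extracellular matrix and adhesion, mesenchymal cells, smooth muscle, epithelial cells, neural cells, hepatoblast, germ cells, dissociation stress and mitochondrial genome. Members were counted by the gene test, adjusted over all genes and adjusted over the list alone. A list of at least 3 tested members was also tested with camera, with a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1). In the comparisons with 1 library on each side, the median log2 ratio of a list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression.

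The genes named were those with the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups. Predicted genes (Gm and Rik symbols) and hemoglobin genes were left out. From each list 2 to 4 passing members with the highest CPM were added, and 17 genes of the transition, Runx1 among them, could be named in every comparison. With 1 library on each side the 8 largest CPM ratios each way were taken, with at least 100 UMIs in the higher library. Positions are from GENCODE vM21 on mm10, which held 249 of the 250 named genes looked up. A 3′ kit counts the ends of transcripts. Overlapping genes and near-identical copies therefore share reads in ways the matrix does not show.

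Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma on mean CPM per cell, fits on the compared groups alone, sums over annotated endothelial and EHT cells alone, a replicate block, other minimum cell numbers, counts thinned to one total within a library, added or left-out libraries, and other denominators of the shares. The tests were tried on counts simulated from the real means and library sizes with known changes. Of 50 genes changed by 4-fold, the whole-library test recovered 66% for HE against E at E9.5, 34% for HE against E at E10.5, 14% for IAC at E11.5 against E10.5 and 46% for Runx1+/- against Runx1+/+. For the steps between types it recovered 100%, 94%, 84% and 82% in their order along the transition. Of the calls on simulated counts, 3.49% (HE against E at E9.5) to 16% (the interaction) were false for whole libraries and 4.86% (Conflux endo against Endo) to 11.5% (HE against Pre-HE) for the steps, some above the 5% the adjustment aims at. For HE against E at E10.5 it was 10.8%. The added fits on IAC cells and on Wnt_high endothelium were not simulated.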

Results

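Single-cell transcriptomes were collected from mouse embryos to follow arterial endothelium as it turns into blood. The series asked which expression profiles mark endothelial cells (E), hemogenic endothelium (HE) and intra-arterial clusters (IAC) at E9.5, E10.5 and E11.5, and how they relate to stem cells of the E14.5 fetal liver. E and HE were parted by a Runx1:GFP reporter, since Runx1 encodes the transcription factor that endothelial cells need to form blood. IAC cells were sorted on Kit. Other libraries held the whole E+HE+IAC gate, wild-type, CD44-selected, split by artery, or with 1 Runx1 allele lost. The 26 libraries held 182 to 4845 cells, 2895176 to 59879972 UMIs and a median of 5459 to 26246 UMIs per cell.

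The sorted gates differed in what they contained, by the authors' annotation. HE cells made up 33.3% of the 171 annotated cells in E9.5 HE replicate 1 (95% interval 26.3 to 40.9) and 86.4% of the 648 in replicate 2 (83.5 to 89.0). The E10.5 HE library held 32.4% HE cells (30.3 to 34.7) and 59.8% IAC cells (57.5 to 62.1). Mesenchymal and other contaminating cells took 56.9% of E9.5 E replicate 1 (54.4 to 59.4), 70.1% of E10.5 E replicate 2 (67.1 to 73.0) and 56.6% of E11.5 IAC replicate 2 (50.1 to 62.9). In E11.5 IAC replicate 1, 93.1% of cells carried no type (91.5 to 94.4). No cell of the cR1 libraries carried one. Replicate 1 of E and HE was gated on CD31, and replicate 2 on CD144 and ESAM with Ter119+ cells excluded, so the replicate number goes with the gate.

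**Figure D1:**
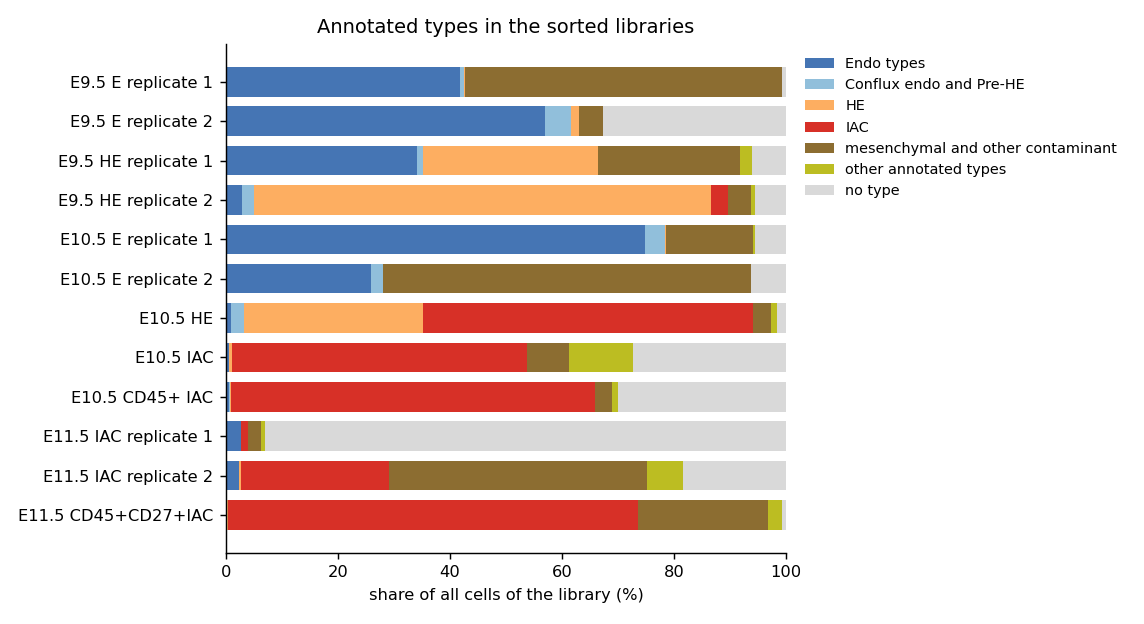
Share of all cells of each sorted library (horizontal axis, percent) by the authors' annotated type, 1 bar per library, with related types joined and cells without a type in grey. Contaminating cells take 56.5% of E9.5 E replicate 1 and 65.8% of E10.5 E replicate 2, and 93.1% of cells in E11.5 IAC replicate 1 have no type.

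At E10.5 Endo, Conflux endo, Pre-HE, HE and IAC were ordered along the transition, and each was compared with the type before it within libraries. Endo was not a single type of the authors but pooled their Endo (Wnt_low), Endo (Wnt_high) and Endo (other). Conflux endo, the first type after Endo, was marked by arterial genes. Gja5, which encodes the arterial gap junction protein connexin 40 (chromosome 3, 96904693 to 97077416, plus strand), stood at 378 ± 105 CPM (counts-per-million) in Conflux endo against 1.87 ± 1.88 CPM in Endo (SD, n = 6 libraries each). Its log2 fold change was 7.57 with an SE of 0.22 (adjusted p = 1.49e-30, edgeR), and it was higher in 6 of 6 libraries. Tmem100, a BMP-responsive arterial gene, rose from 2.53 to 136 CPM, the Wnt antagonist Dkk2 by a log2 fold change of 6.00 and the Notch target Hes5 by 5.89. The receptor gene Cd44, whose protein was used to sort only the CD44+ library among these, rose from 1.27 ± 0.71 to 41.3 ± 11.6 CPM. Nr2f2, the regulator of venous identity (chromosome 7, 70351944 to 70366735, minus strand), fell from 95.1 to 6.57 CPM, and the apelin receptor gene Aplnr fell from 294 ± 60.1 to 10.1 ± 11.6 CPM. Odc1, a MYC target that makes polyamines, fell from 249 to 21.1 CPM. Bmp4, Nrp2, Mafb and Phgdh, of serine synthesis, also fell, with log2 fold changes of -3.54, -3.37, -3.33 and -4.41. In Conflux endo UMIs of Mafb came from the E10.5 E+HE+IAC library alone, with a log2 difference of -2.57 there. Runx1 (chromosome 16, 92601466 to 92826149, minus strand) stood at 0.345 CPM in Conflux endo and 1.55 CPM in Endo and did not pass (adjusted p = 0.507).

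Several gene groups moved largely one way in this first step. All 21 arterial genes tested rose, also adjusted over the list alone, with a median log2 fold change of 2.87 (adjusted p = 0.00215 with an estimated correlation), Gja4 by 4.68 and Hey1 by 3.59. Of 13 venous and lymphatic genes 11 fell by either adjustment (median -2.54, adjusted p = 0.0515 with an estimated correlation). Proliferation genes fell together: 26 of 26 S phase genes (median -1.30, adjusted p = 0.0515 with an estimated correlation) and 26 of 26 G2M genes (median -1.27, adjusted p = 0.022), with the same counts adjusted over the list alone. With Endo restricted to the types marked [AE], 85 of the 105 S phase, G2M, MYC and ribosomal protein genes fell, by a median of -0.552 against -1.19. The mitotic kinase gene Cdk1 fell with a log2 fold change of -1.20. MYC and ribosome biogenesis genes fell in 23 of 24 cases and 24 adjusted over the list alone (median -1.34, adjusted p = 0.022 with an estimated correlation), Npm1 by a log2 fold change of -1.34 and Ncl of -1.35. Ribosomal protein genes fell in 29 of 29 cases by a smaller median of -0.46, without a call when the correlation was estimated (adjusted p = 0.105). Extracellular matrix and adhesion genes rose in 15 of 17 cases and fell in 1, or 2 adjusted over the list alone (median 1.32, adjusted p = 0.022 with an estimated correlation), led by Sparc at 1.32 and Col18a1 at 1.86. Contractile genes of the smooth muscle list rose in 4 of 6 cases, among them Myl9 at 3.71 and Tagln at 3.80, and inflammatory and interferon genes rose in 10 of 17 cases and 11 adjusted over the list alone (adjusted p = 0.0515 for each with an estimated correlation). Pan-endothelial genes rose in 14 of 18 cases and fell in 1 (adjusted p = 0.0515 with an estimated correlation). Glycolysis genes fell in 13 of 19 cases and rose in 3 (adjusted p = 0.262), and oxidative phosphorylation genes fell in 18 of 25 and rose in 1 (adjusted p = 0.325, both with an estimated correlation). Dissociation stress genes, which can rise while tissue is digested, rose in 5 cases and fell in 7 of 16 (adjusted p = 0.9), and mitochondrial genes rose in 5 and fell in 1 of 13 (adjusted p = 0.478).

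In all, 4304 of 10820 genes changed between Endo and Conflux endo in edgeR's quasi-likelihood test, 1838 up and 2466 down, against 2047 up and 1786 down with DESeq2. With Endo restricted to the types marked [AE], 2123 genes changed, 867 up and 1256 down. Of the 4304 calls 1863 were called again, and 165 had the other sign there, whether called or not. Without the E10.5 E+HE+IAC library, which held most Conflux endo cells, 2620 of the 6400 genes then tested changed.

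Pre-HE cells differed from Conflux endo by the first rise of Runx1, from 0.345 ± 0.844 to 6.39 ± 4.65 CPM (SD, n = 6 each), a log2 fold change of 2.74 with an SE of 0.70 (adjusted p = 0.00467, edgeR), higher in 5 of 6 libraries. Htra1, a secreted protease, rose from 3.16 ± 4.41 to 153 ± 39.7 CPM, Eln, which encodes elastin, from 0.0689 to 32.3 CPM, and the keratin gene Krt18 from 0.658 to 46.9 CPM. Cytl1, encoding a secreted cytokine-like protein, had 38.8 ± 24.8 CPM in Pre-HE and no UMI in Conflux endo, at least 41.5-fold higher. Gja5 rose further, from 378 to 602 ± 176 CPM, and Cd44 from 41.3 to 70.2 CPM. The gap junction gene Gja1 fell from 328 ± 105 to 29.4 ± 12.9 CPM, the glucose transporter gene Slc2a1 from 792 ± 245 to 101 ± 41.7 CPM, and Hes5, Esm1 and Rgs16 by log2 fold changes of -4.35, -3.12 and -3.08.

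Among 24 hemogenic and EHT regulators 14 rose and 1 fell in Pre-HE, and 15 rose adjusted over the list alone (median 1.02, adjusted p = 0.023 with an estimated correlation), Lyl1 by 1.26 and Cbfa2t3 by 1.22. Shear stress response genes rose in 7 of 10 cases by either adjustment (median 0.91), among them the flow-induced factor Klf2 at 0.90, Tm4sf1 at 1.81 and Pi16 at 4.24 (adjusted p = 0.105 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 19 cases and 14 adjusted over the list alone (median -0.65), with Hmgcs1 at -0.90 and Fdps at -0.80, and glycolysis genes in 8 of 19 and 10 adjusted over the list alone, with Pkm at -0.97. Neither list kept its call with an estimated correlation (adjusted p = 0.274 for both). Arterial genes divided, with 5 up and 7 down of 21. Of 24 HSC-associated genes 10 rose and 3 fell (adjusted p = 0.274 with an estimated correlation). Megakaryocyte genes divided too, with 4 up and 3 down of 13, and 3 of 4 mesenchymal genes rose (adjusted p = 0.294 with an estimated correlation). The test called 1406 of 10820 genes in this step, 685 up and 721 down, and 807 of 6400 tested without the E10.5 E+HE+IAC library. With a minimum of 50 cells per type, Conflux endo came from that library alone.

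HE cells carried the blood-forming regulators. Runx1 stood at 146 CPM in HE against 6.39 ± 4.65 CPM in Pre-HE (SD, n = 6, against 1 library of HE), a log2 fold change of 3.86 with an SE of 0.34 (adjusted p = 2.57e-11, edgeR). Gfi1, the repressor that shuts off endothelial genes downstream of Runx1 (chromosome 5, 107716657 to 107726036, minus strand), rose from 1.45 ± 2.37 to 65.2 CPM, the myeloid factor gene Spi1 from 3.41 to 95.5 CPM and the progenitor factor gene Myb from 0.782 to 32.6 CPM. Sfrp2, a secreted Wnt modulator, rose from 5.31 to 116 CPM and Nupr1, a stress-response coactivator, from 8.05 to 111 CPM. Gja5 fell from 602 to 194 CPM. Tppp3, Tmem255b, Pdlim3 and Wfdc1 had no UMI in HE and were at least 9.41-fold, 8.65-fold, 8.11-fold and 7.36-fold lower there.

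Endothelial genes fell and growth genes rose in the HE library. Pan-endothelial genes fell in 18 of 18 cases by either adjustment (median -0.93, adjusted p = 0.00106 with an estimated correlation) and arterial genes in 18 of 21, or 20 adjusted over the list alone (median -1.23, adjusted p = 0.00412), Gja4 by a log2 fold change of -1.82. RUNX1 targets rose in 8 of 15 cases by either adjustment (median 1.98, adjusted p = 0.00106) and hemogenic and EHT regulators in 12 of 24 (median 1.05, adjusted p = 0.00292), with Mycn at 3.57 and Ikzf2 at 1.84. S phase genes rose in 16 of 26 cases and 24 adjusted over the list alone (adjusted p = 0.0398), MYC and ribosome biogenesis genes in 17 of 24 and 20 adjusted over the list alone (adjusted p = 0.0169), with Npm1 at 1.06. Ribosomal protein genes rose in 24 of 29 and 29 adjusted over the list alone, without a call when the correlation was estimated (adjusted p = 0.0959). For G2M genes edgeR gave 0 of 26 by either adjustment. Shear stress response genes fell in 6 of 10 cases (adjusted p = 0.0216), extracellular matrix genes in 10 of 17 with 1 up (adjusted p = 0.0176), and pan-hematopoietic genes rose in 4 of 21, 5 adjusted over the list alone (adjusted p = 0.0174), Coro1a by 3.67 and Ptpn6 by 2.27, all with an estimated correlation. The step held 884 changed genes, 462 up and 422 down. HE entered from the E10.5 E+HE+IAC library alone, with 86 cells and 1288641 UMIs, so the SE and p hold no spread between HE libraries. With the sorted libraries and E9.5 E+HE+IAC added, 5 libraries of HE against 8 of Pre-HE gave 1959, and Runx1 rose from 13.5 ± 23 to 115 ± 38.8 CPM (log2 fold change 3.16, adjusted p = 2.59e-08, edgeR), Gfi1 by 3.65 and Spi1 by 3.74. HE came here also from E9.5 HE replicates 1 and 2 and E9.5 E+HE+IAC, and Pre-HE from E9.5 E replicate 2, so stages are mixed. Only E10.5 HE and E10.5 E+HE+IAC gave both types. In that fit pan-endothelial genes fell in 17 of 18 cases (median -0.98, adjusted p = 7.33e-05 with an estimated correlation) and arterial genes in 19 of 21 (median -1.08, adjusted p = 0.0136), while S phase genes rose in 24 of 26 (median 0.80, adjusted p = 0.0088) and MYC and ribosome biogenesis genes in 19 of 24 (median 0.74, adjusted p = 0.0274, all with an estimated correlation).

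IAC cells lost endothelial genes and took on blood genes. Ptprc, which encodes the leukocyte antigen CD45, stood at 23.2 ± 8.75 CPM in IAC (SD, n = 4) with no UMI in the HE library, at least 9.84-fold higher. Serpinb1a, Cd52 and Rgs1 were likewise absent in HE and at least 13.1-fold, 9.30-fold and 8.28-fold higher. Spi1 rose from 95.5 to 238 CPM, Kit, the stem cell factor receptor gene, from 32.6 to 72.6 CPM, and Hlf, a stem cell transcription factor gene, from 20.2 to 61.1 CPM. Gfi1 fell from 65.2 to 25.6 CPM (adjusted p = 0.0203, edgeR). Ctsh, a lysosomal protease gene, fell from 270 to 8.52 ± 1.77 CPM, Tmem100 from 122 to 3.23 CPM and Sost, a Wnt antagonist gene, from 89.3 to 0.997 CPM. Ankrd1 was at least 85.2-fold lower, with no UMI in IAC. Runx1 stood at 125 ± 13.8 CPM in IAC and 146 CPM in HE. In the fit with the library term its log2 fold change was positive, against these means, and did not pass, so no direction is read from it.

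Pan-endothelial genes fell in 16 of 18 cases and 17 adjusted over the list alone (median -1.72, adjusted p = 0.000138 with an estimated correlation), the tight junction gene Cldn5 by a log2 fold change of -2.84. Arterial genes fell in 18 of 21 by either adjustment (median -3.08, adjusted p = 0.000353), TGF-beta and BMP response genes in 11 of 15 (median -1.98, adjusted p = 0.000949), Id3 by a log2 fold change of -2.80, and extracellular matrix genes in 14 of 17 with 1 up (adjusted p = 0.000949). Pan-hematopoietic genes rose in 14 of 21 cases and fell in 1, with 17 up adjusted over the list alone (adjusted p = 0.000138), Rac2 by 5.84 and Coro1a by 2.55. Their median was 2.25, or 1.94 with members absent on one side at their bound. Myeloid genes rose in 7 of 10 cases and 8 adjusted over the list alone (adjusted p = 0.000949), Prtn3 and Fcer1g both by 5.71, and lymphoid genes in 3 of 10 and 5 adjusted over the list alone (adjusted p = 0.0325), Ltb by 2.32 and Lsp1 by 1.89, all with an estimated correlation. MYC and ribosome biogenesis genes rose in 13 of 24 and 19 adjusted over the list alone (adjusted p = 0.0569 with an estimated correlation). HSC-associated genes divided, with 8 up and 5 down of 24 (adjusted p = 0.714 with an estimated correlation). The step held 1586 changed genes, 571 up and 1015 down, against the same single HE library. With the sorted libraries and E9.5 E+HE+IAC added, 6 libraries of IAC against 5 of HE gave 3664, and Ptprc rose by 5.44, Spi1 by 1.72 and Kit by 1.08, while Gfi1 fell with a log2 fold change of -0.88. That fit mixes stages too, with HE also from E9.5 HE replicates 1 and 2 and E9.5 E+HE+IAC, and IAC from E9.5 HE replicate 2.

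**Figure D2:**
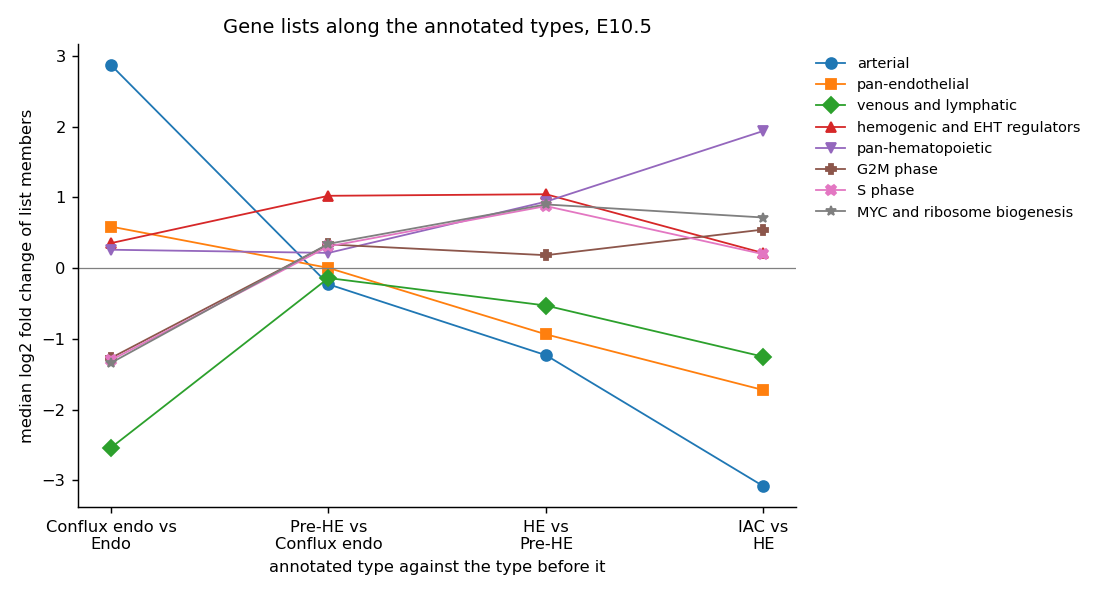
Median log2 fold change (vertical axis) of the members of 8 gene lists in each annotated type against the type before it at E10.5 (horizontal axis), 1 line per list, with members absent on one side placed at their bound. Arterial genes stand at 2.87 in the first step and at -3.08 in the last, while S phase, G2M and MYC genes lie below 0 in the first step alone.

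At E9.5 the HE and E gates were compared to ask what sets hemogenic endothelium apart when it first appears. Runx1 averaged 68.3 ± 63.6 CPM in the HE libraries and 1.82 ± 0.57 CPM in the E libraries (SD, n = 2 each). Within the CD31 gate it stood at 23.4 CPM in HE and 1.42 CPM in E, and within the CD144 gate at 113 and 2.22 CPM. Over all cells no gene passed in the fit without a block: edgeR called 0 of 16920 genes, with 1227 below an unadjusted p of 0.05, while DESeq2 called 138 (118 up, 20 down) and limma 2. With the replicate number, which carries the gate in both groups, as a block, edgeR called 105 genes, 97 up and 8 down. The block fit held these libraries alone and had 1 residual degree of freedom, against 6 in the main fit. With all cells, 13 of 25 hemogenic and EHT regulators rose adjusted over the list alone, against 0 over all genes (median 1.37, adjusted p = 0.364 with an estimated correlation), and 6 of 21 arterial genes did (median 1.07, adjusted p = 0.364). In the same sums 16 of 22 erythroid genes rose adjusted over the list alone, with a median of 5.40 and 0 over all genes (adjusted p = 0.364 with an estimated correlation). Contaminating cells made up 56.9% of the annotated cells in E replicate 1 and 26.9% in HE replicate 1.

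Restricted to cells annotated as endothelial or EHT types, 133 genes passed at E9.5, 119 up and 14 down. Gfi1 stood at 27.2 ± 23.6 CPM in HE without a UMI in E. Runx1 rose from 2.03 ± 0.56 to 72.8 ± 61.6 CPM (SD, n = 2 each), a log2 fold change of 5.23 with an SE of 0.75 (adjusted p = 0.0113, edgeR). Spi1 rose from 0.654 to 28.2 CPM, Cd44 from 4.71 to 52.2 CPM, Nupr1 by a log2 fold change of 8.93, the integrin gene Itgb3 by 5.60 and the Ikaros family gene Ikzf2 by 5.80. Mafb, the amino acid synthesis gene Asns and St3gal6 fell, with log2 fold changes of -2.58, -1.63 and -1.43. Of the hemogenic and EHT regulators 9 of 24 rose, 16 adjusted over the list alone (adjusted p = 0.166 with an estimated correlation), and of the arterial genes 4 of 21 rose, 12 adjusted over the list alone (adjusted p = 0.211). One model of the annotated Endo and HE cells, with 4 and 3 libraries at E9.5, called 1780 genes, 1073 up and 707 down. E9.5 HE replicate 1 and E9.5 E+HE+IAC gave cells of both types to this model, which had no library term. There Gja5 rose from 1.86 to 231 ± 171 CPM and Runx1 from 2.28 ± 1.15 to 86.9 ± 33.1 CPM (adjusted p = 8.38e-08, edgeR), while Nr2f2, Aplnr and the cyclin gene Ccnd1 fell, with log2 fold changes of -4.72, -5.42 and -4.29. Arterial genes rose in 15 of 21 cases and 17 adjusted over the list alone (adjusted p = 0.0356 with an estimated correlation), hemogenic regulators in 16 of 24 with 1 down (adjusted p = 0.0229) and HSC-associated genes in 13 of 25 with 1 down (adjusted p = 0.0291). Venous and lymphatic genes fell in 9 of 14 and 10 adjusted over the list alone (adjusted p = 0.0298), and MYC and ribosome biogenesis genes in 14 of 24 and 23 adjusted over the list alone (adjusted p = 0.0707, all with an estimated correlation). Smooth muscle genes rose in 4 of 7 cases and fell in 1 (median 4.22, adjusted p = 0.106 with an estimated correlation). Of the other cells' markers 2 of 6 epithelial genes rose, Krt18 by 4.55, and 1 of 14 mesenchymal genes (median 0.91, adjusted p = 0.66 with an estimated correlation), while neural genes had 1 up and 1 down of 5, hepatoblast genes 1 up of 3 and germ cell genes 0 of 5 with 0 adjusted over the list alone (edgeR). Without HE replicate 2 the model called 555 genes.

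At E10.5 genes of blood cells were among the largest rises from the E to the HE gate, and the venous regulator gene Nr2f2 among the largest falls. Gfi1 stood at 40.8 CPM in HE and 0.0372 ± 0.0527 CPM in E (SD, n = 2, against 1 library of HE; adjusted p = 0.0447, edgeR). Lyz2, the lysozyme gene of myeloid cells (chromosome 10, 117277331 to 117282321, minus strand), stood at 112 and 0.102 CPM (log2 fold change 10.13, adjusted p = 0.0376), and the thrombopoietin receptor gene Mpl and the megakaryocyte factor gene Nfe2 rose by log2 fold changes of 8.83 and 8.11. Tuba8, a tubulin gene, had no UMI in E and was at least 118-fold higher in HE. Nr2f2 fell from 88.8 ± 24.1 to 1.85 CPM and the cadherin gene Cdh2 by a log2 fold change of -4.63. Runx1 stood at 111 and 2.01 ± 0.64 CPM and missed the threshold over all cells (adjusted p = 0.057). In the HE library 59.8% of annotated cells were IAC, so the difference spans both types.

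Of 16920 genes 200 changed, 103 up and 97 down, in a fit with 6 residual degrees of freedom. RLE size factors gave 65 up and 96 down and moved the median of all genes by -0.143 on the log2 scale, while DESeq2 gave 631 up and 1154 down, including all 200. Hemogenic regulators rose in 3 of 25 cases over all genes and 18 adjusted over the list alone, RUNX1 targets in 3 of 16 and 14 adjusted over the list alone, megakaryocyte genes in 5 of 18 and 9 adjusted over the list alone, and myeloid genes in 2 of 20 and 12 adjusted over the list alone (adjusted p = 0.214 for each with an estimated correlation). Venous and lymphatic genes fell in 3 of 14 and 13 adjusted over the list alone (adjusted p = 0.214). Neural genes fell in 0 of 11 over all genes and 2 adjusted over the list alone (edgeR, median -4.18, adjusted p = 0.223 with an estimated correlation). Contaminating cells made up 70.1% of the annotated cells in E replicate 2. Without E replicate 2 the test called 0 genes with 2150 below an unadjusted p of 0.05, and without E replicate 1 it called 6. Summed over annotated endothelial and EHT cells, 1780 genes passed, 734 up and 1046 down, Runx1 among them from 1.33 ± 1.11 to 110 CPM (adjusted p = 0.00208, edgeR). There Spi1 rose from 0.240 to 232 CPM, Cd44 from 5.37 to 86.2 CPM and Kit from 5.34 to 55.5 CPM. Aplnr and Gpr183 fell, with log2 fold changes of -7.65 and -7.88, and Rac2, Ccl9 and Ikzf1 had no UMI in E and were at least 239-fold, 114-fold and 81.4-fold higher in HE.

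Endothelium itself was compared between E10.5 and E9.5 to ask how the starting cells differ with age. Over all cells of the E gates edgeR called 0 genes, with 784 below an unadjusted p of 0.05, while DESeq2 called 6 and limma 0. Runx1 stood at 2.01 ± 0.64 and 1.82 ± 0.57 CPM (SD, n = 2 each, adjusted p = 1, edgeR). Annotated Endo cells of the libraries with intact Runx1 and at least 20 such cells, 8 at E10.5 and 4 at E9.5, gave 1661 genes, 915 up and 746 down. The types within Endo differed between the stages: Endo (other) made up 65% of annotated cells in E9.5 E+HE+IAC and 20.8% in E10.5 E+HE+IAC, Wnt_high 2.68% and 19.9%, and Wnt_low 2.77% and 25.4%, so stage and mix of types are not told apart here. Cav1, the main coat protein of caveolae, rose from 13.2 to 73.4 CPM, and Procr, the endothelial protein C receptor gene, by a log2 fold change of 1.97. Etv2, which starts endothelial fate, fell from 28.3 ± 8.22 to 2.83 ± 1.32 CPM, Lin28a, a regulator of embryonic timing, from 22.8 to 3.41 CPM, and the hexokinase gene Hk2 by a log2 fold change of -2.75. Glycolysis genes fell in 11 of 20 cases and 12 adjusted over the list alone, Eno1 by a log2 fold change of -0.89 and Ldha of -0.63, and MYC and ribosome biogenesis genes in 10 of 24 and 14 adjusted over the list alone (adjusted p = 0.296 for both with an estimated correlation). Inflammatory and interferon genes rose in 6 of 19 and fell in 1 (adjusted p = 0.605), and lymphoid genes rose in 3 of 10 (adjusted p = 0.296 with an estimated correlation). Among markers of other cells, mesenchymal genes had a median of -1.45 with 1 of 14 down, smooth muscle genes of -0.85 with 3 of 7 down, and neural genes of 1.21 with 1 up and 1 down of 5 (adjusted p = 0.905 for each with an estimated correlation). Without E9.5 E replicate 2 the model called 1060 genes, and without replicate 1 it called 1107.

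HE cells also changed between the stages. Annotated HE cells of 2 libraries at E10.5 and 3 at E9.5 gave 145 genes, 58 up and 87 down. Procr rose from 58.9 to 249 CPM, Hlf from 6.04 to 28.3 CPM and Pdzk1ip1, which encodes a small membrane protein, from 3.25 to 30.6 CPM, while Tubb2b and Gap43, both known from neurons, and Pcsk1n fell, with log2 fold changes of -2.53, -1.92 and -4.03. HSC-associated genes rose in 6 of 25 cases and 9 adjusted over the list alone (adjusted p = 0.0658 with an estimated correlation), and hemogenic regulators in 2 of 24 and 14 adjusted over the list alone (adjusted p = 0.121), Myb by 1.81. Dissociation stress genes had a median of 0.86 with 0 of 16 past over all genes and 1 adjusted over the list alone, and mesenchymal genes of -1.86, or -1.97 with members absent on one side at their bound, with 0 of 14 by either adjustment (edgeR, adjusted p = 0.365 and 0.45 with an estimated correlation). Runx1 gave a log2 fold change of 0.63 (adjusted p = 0.539, edgeR). The difference between HE and Endo also differed between stages, tested as an interaction, in 148 genes, with the same difference in the types within Endo. It was larger at E10.5 for 52, led by Ifitm1 at 3.46 and Sfrp2 at 3.33, and lower for 96, among them Cav1 at -3.08. MYC and ribosome biogenesis genes passed upward in 2 of 24 cases and 19 adjusted over the list alone (adjusted p = 0.146 with an estimated correlation). Over all cells of the sorted libraries the interaction gave 0 genes in edgeR, with 1985 below an unadjusted p of 0.05, 371 in DESeq2 and 0 in limma. Without the E10.5 HE library edgeR called 0 genes between the stages and 1 for the interaction, and without the E10.5 E+HE+IAC library 363 and 249. Without E9.5 HE replicate 1 there were 16 for either, and without E9.5 E+HE+IAC 34 and 37. Without E9.5 E replicate 1 the interaction had 67.

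IAC cells at E11.5 were set against those at E10.5 as stem cells emerge. Annotated IAC cells of 2 libraries at E11.5 and 7 at E10.5 gave 788 genes, 330 up and 458 down. Of the 2 libraries 1 was gated on CD45 and CD27, so stage and gate are partly confounded and the changes below cannot be laid to stage alone. Hlf rose from 56.0 ± 13.5 to 119 ± 2.65 CPM (SD, adjusted p = 0.0122, edgeR), Mllt3, which sustains stem cell self-renewal, from 19.2 to 55.0 CPM, the stem cell regulator gene Mecom by a log2 fold change of 1.51, and Kit from 70.8 to 112 CPM. Ramp1 rose from 21.7 to 97.2 CPM and Pdzk1ip1 from 21 to 76.5 CPM. The matrix link protein gene Hapln1, the Fc receptor gene Fcgr3 and Asns fell, with log2 fold changes of -3.19, -2.19 and -1.69. HSC-associated genes rose in 7 of 25 cases and 11 adjusted over the list alone (median 0.51, adjusted p = 0.00425 with an estimated correlation). MYC and ribosome biogenesis genes fell in 15 of 24 and 19 adjusted over the list alone (median -0.67, adjusted p = 0.00555), Srm by a log2 fold change of -1.18 and Ncl of -0.72. S phase genes fell in 8 of 26 and 15 adjusted over the list alone, and glycolysis genes in 6 of 19 and 11 adjusted over the list alone (adjusted p = 0.161 for both with an estimated correlation). Interferon genes rose in 5 of 16 and 7 adjusted over the list alone, Irf9 by 1.59 and Stat1 by 1.23 (adjusted p = 0.0832 with an estimated correlation). Runx1 stood at 116 and 119 CPM (adjusted p = 0.914). Without the CD45+CD27+ IAC library 4 genes passed, and without E11.5 IAC replicate 2, 215. Without the E10.5 IAC library 1153 passed, and without E10.5 HE 521.

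For the IAC gates as sorted the tools differed between the stages. Over all cells edgeR called 0 genes for E11.5 against E10.5 IAC, with 1530 below an unadjusted p of 0.05, DESeq2 166 and limma 7, and Runx1 stood at 24.8 ± 30.7 CPM (SD, n = 2) and 106 CPM. Macrophage genes fell in 0 of 13 cases over all genes and 7 adjusted over the list alone (adjusted p = 0.364 with an estimated correlation). Replicate 1, in which 93.1% of cells carried no type, had Runx1 at 2.95 plain CPM, and replicate 2 at 45.5. The CD45+CD27+ gate at E11.5, which enriches stem cell precursors, gave 0 genes in edgeR against E11.5 IAC, with 1435 below an unadjusted p of 0.05, while DESeq2 called 331 (16 up, 315 down) and limma 51. Venous and lymphatic genes fell there in 0 of 14 cases over all genes and 12 adjusted over the list alone (median -3.58, adjusted p = 0.382 with an estimated correlation). Restricted to annotated endothelial and EHT cells, 23 genes fell and none rose. Lyve1+ endothelium made up 34 of 88 annotated cells in E11.5 IAC replicate 1, 7 of 244 in replicate 2 and 0 of 277 in the CD45+CD27+ library. Among them the liver endothelial gene Oit3, the receptor gene Gpr182 and the adrenomedullin gene Adm had no UMI in the CD45+CD27+ library and were at least 197-fold, 114-fold and 57.1-fold lower, and the lymphatic receptor genes Lyve1 and Stab2 fell from 76.4 to 0.929 CPM and from 59.6 to 0.620 CPM. Without E11.5 IAC replicate 2 edgeR called 440 genes over all cells for this gate and, 108 for the stages.

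**Figure D3:**
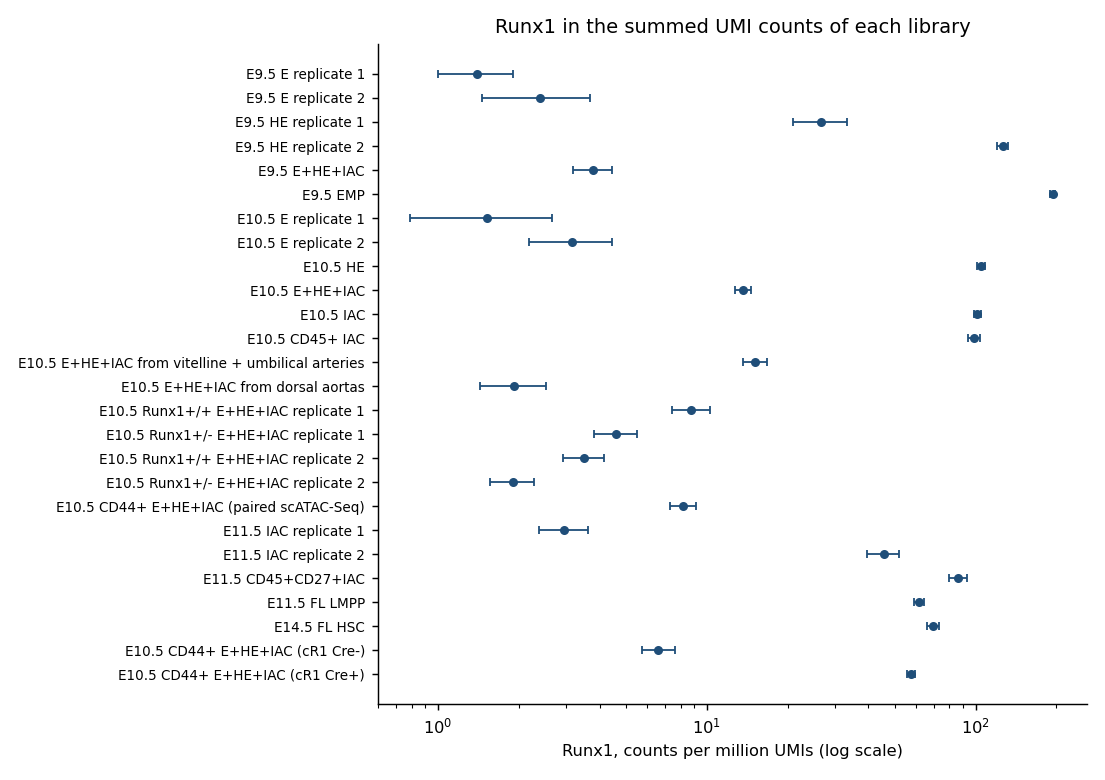
Runx1 in plain CPM (horizontal axis, log scale) over all cells of each of the 26 libraries, with exact 95% Poisson bars for counting error. The E libraries lie between 1.41 and 3.17 CPM, and the E10.5 HE library at 105 CPM.

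Loss of 1 Runx1 allele was compared with intact Runx1 at E10.5 to ask how gene dose acts on the transition. HE and IAC cells made up 1.80 ± 0.558% of annotated cells in the Runx1+/+ libraries and 0.383 ± 0.0319% in the Runx1+/- libraries (SD, n = 2 each), in ratios of 0.185 and 0.256 within replicates 1 and 2. IAC cells alone were 1.26 ± 0.0215% and 0.263 ± 0.0282%. Pre-HE cells were 2.46 ± 1.26% and 3.29 ± 1.31%, higher in Runx1+/- in both replicates, with ratios of 1.26 and 1.51. Conflux endo cells were 2.12 ± 0.768% and 2.24 ± 1.64%. Lyve1+ endothelium was 1.30 ± 0.206% and 0.445 ± 0.171%, and myeloid progenitors 2.93 ± 3.38% and 0.556 ± 0.131%. The exact two-sided permutation p was 0.333 for HE with IAC, for IAC, for HE and for Lyve1+ endothelium, the smallest that 2 libraries against 2 allow, 0.667 for Pre-HE and 1 for Conflux endo. The shares rest on 11 and 30 IAC cells in Runx1+/+ and 3 and 11 in Runx1+/-, and on 8 and 4 HE cells against 2 and 3.

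**Figure D4:**
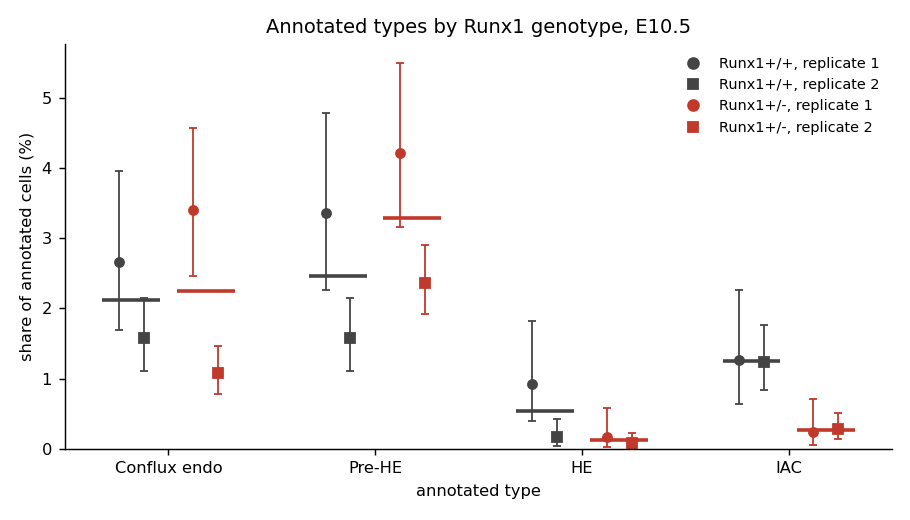
Share of annotated cells (vertical axis, percent) for 4 annotated types in each Runx1+/+ and Runx1+/- library at E10.5 (points), with exact 95% binomial bars for counting error and lines at the group means. IAC means are 1.26% and 0.263%, while Pre-HE means are 2.46% and 3.29%.

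Within the 7 types tested, HE and IAC not among them, edgeR with its low-count filter and without a block called no gene. Other settings called some. Runx1 over all cells stood at 5.85 ± 2.45 CPM in Runx1+/+ and 3.16 ± 1.44 CPM in Runx1+/- (SD, n = 2 each, adjusted p = 1, edgeR). A 3′ tag can lie outside the altered part of the allele, so this level need not check the labels. In IAC cells Runx1 stood at 49.9 and 106 plain CPM in Runx1+/+ and 124 and 43.4 in Runx1+/-. Over all cells edgeR called 0 genes, with 75 below an unadjusted p of 0.05, DESeq2 3 and limma 0. Within the 7 annotated types edgeR called 0 genes each, with 36 to 191 below an unadjusted p of 0.05. Over all 7 DESeq2 called 4, all of them in contaminating cells. Without the filter edgeR called 77, of which 68 were in contaminating cells. The types were Conflux endo, Pre-HE, Endo (low quality), Endo (other), Endo (Wnt_high), Endo (Wnt_low) and contaminating cells. HE and IAC, where Runx1 stood far higher than in these, had too few cells to test, so a dose effect inside them was not examined. With 1 library left out genes did pass, many of them in contaminating cells. There 1 library stood alone in its genotype, so the counts are not given and no dose effect is read from them. Cells without a type made up 10.2% and 9% of the replicate 1 libraries and 1.31% and 1.52% of the replicate 2 libraries. With a replicate block 90 genes passed over the 7 types, 50 of them in Endo (Wnt_high) and 25 in contaminating cells. The fits within types had 2 residual degrees of freedom, and a block or a library left out took 1 of them. Myeloid genes had a median of -1.77 over all cells and macrophage genes of -2.04, with 0 members past over all genes (adjusted p = 0.16 and 0.576 with an estimated correlation). In sum macrophage genes stood at 498 and 84.8 plain CPM in Runx1+/+ and 117 and 90.7 in Runx1+/- (replicates 1 and 2), and myeloid genes at 442 and 107 against 94.5 and 69.7, so the difference lay mostly in Runx1+/+ replicate 1, where 46 of 865 annotated cells were myeloid progenitors. RUNX1 targets and pan-hematopoietic genes had medians of -1.09 and -1.02 (adjusted p = 0.78 for both).

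The remaining comparisons had 1 library on each side and no test, so they compare those libraries in plain CPM. In the cR1 mice, which carry a RUNX1 transgene at ROSA26 with or without a Cdh5-driven Cre, Runx1 stood at 57.6 CPM in Cre+ (95% Poisson interval 55.5 to 59.8) and 6.63 CPM in Cre- (5.74 to 7.61), 8.69-fold higher. Reads of the human transgene may be partly counted as mouse Runx1. Gfi1 stood at 1.49 and 1.46 CPM, Spi1 at 7.47 and 9.54 CPM, and Itgb3 at 4.38 and 0.497 CPM. The fatty acid carrier gene Fabp4 was lower in Cre+, at 8.92 against 19.0 CPM, as was the heat shock gene Hspb1, at 11.8 against 25.9 CPM. MYC and ribosome biogenesis genes were higher in 23 of 24 cases by a median of 0.15, at percentile 100 of random lists of like expression. Pan-endothelial genes were lower in 17 of 18 cases (median -0.14) and extracellular matrix genes in 17 of 18 (median -0.21), both at percentile 0. In this pair 18 lists lay outside the central 95% of random lists. Random lists draw genes singly, so lists whose genes move together can reach such percentiles without an effect of Cre. RUNX1 targets were lower in 12 of 15 cases (median -0.36). Hepatoblast genes were higher in 8 of 8 cases (median 2.40), Afp at 4.03 CPM without a UMI in Cre-, at least 40.6-fold.

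Vitelline and umbilical arteries were set against the dorsal aorta at E10.5. Runx1 stood at 15.2 CPM in the former (13.6 to 16.8) and 1.92 CPM in the aorta (1.44 to 2.52), and Gja5 at 27.4 and 7.02 CPM. The transcription factor gene Hand1 was at 7.67 and 0.0369 CPM, Postn, which encodes the matrix protein periostin, at 29.2 and 0.850 CPM, and Oit3 at 103 and 3.21 CPM. The forkhead genes Foxq1 and Foxf2 and the retinol receptor gene Stra6 were lower, at 0.436 against 12.4 CPM, 0.218 against 5.80 CPM and 0.348 against 9.16 CPM. Pan-hematopoietic genes were higher in 22 of 22 cases (median 1.38), hemogenic regulators in 23 of 24 (median 1.52), shear stress response genes in 11 of 11 (median 1.17) and dissociation stress genes in 16 of 16 (median 1.95). Erythroid genes were lower in 15 of 19 (median -1.63) and neural genes in 7 of 10 (median -1.92). TMM factors shift these log2 ratios by -0.348. Wnt_high endothelium made up 5 of 1152 annotated cells in the arteries and 439 of 1928 in the aorta, Lyve1+ endothelium 175 and 10, and IAC 65 and 16.

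CD45+ IAC were set against all IAC at E10.5. Runx1 stood at 98.9 and 102 CPM, Gfi1 at 15 and 6.36 CPM, Spi1 at 184 and 118 CPM and Il7r, the interleukin 7 receptor gene, at 13 and 5.34 CPM. Chemokine genes were lower in CD45+ IAC, Cxcl2 at 0.130 against 46.8 CPM and Ccl2 at 0.194 against 46.8 CPM, while Gja4 was higher at 16.7 against 2.05 CPM. Macrophage genes were lower in 13 of 13 cases (median -3.85) and dissociation stress genes in 16 of 16 (median -2.57), while pan-endothelial genes were higher in 18 of 18 (median 0.71) and G2M genes in 24 of 26 (median 0.51). Germ cell genes were lower in 6 of 7 cases (median -1.18) and epithelial genes in 6 of 9 (median -0.77). TMM factors shift these ratios by -0.171. The IAC library held 179 myeloid progenitors among 1663 annotated cells. Cells without a type made up 30.1% of the CD45+ IAC library and 27.3% of the IAC library. In these cells pan-endothelial genes summed to 6628 and 4003 CPM, against 2311 and 1625 CPM over all cells. The higher endothelial genes therefore need not lie in IAC cells, which was not tested.

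Fetal liver LMPP at E11.5 were set against fetal liver HSC at E14.5. Stem cell genes stood far lower in LMPP: Mecom at 0.841 against 191 CPM, Hlf at 3.88 against 186 CPM, Procr at 0.518 against 91 CPM and Gata2 at 2.17 against 98.9 CPM. Il7r stood at 76.8 CPM in LMPP with no UMI in HSC, at least 510-fold higher. HSC-associated genes were lower in 24 of 25 cases (median -2.63) and inflammatory and interferon genes in 20 of 24 (median -1.25), while myeloid genes were higher in 18 of 20 (median 2.72) and macrophage genes in 13 of 13 (median 3.20). Hepatoblast genes were higher in 10 of 10 cases (median 7.43), with Ttr at 179 against 0.0502 CPM and Rbp4 at 272 against 0.151 CPM, and erythroid genes in 20 of 22 (median 4.28). Erythroid progenitors made up 22.0% of annotated cells in the LMPP library (20.1 to 24.0) and 0.271% in the HSC library. Runx1 stood at 61.6 and 69.5 CPM, a log2 ratio of -0.18 that becomes 0.30 with TMM factors, which shift all ratios by 0.477.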

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

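All tests weighed below were chosen after the counts had been seen. A single library stood apart in 1 of 32 groups of 4 to 10 libraries tested, about as many as chance gives, since about 1 in 20 such groups has one. For Mafb the log2 difference between Conflux endo and Endo was -2.57 in the E10.5 E+HE+IAC library and -7.22 to -6.20 in the others, where Conflux endo had no UMI of it and the difference is set by an added offset, a gap of 0.782 of the whole range. The difference between HE and Endo cells changed between E9.5 and E10.5 in 148 genes by an interaction test in edgeR. The types within Endo also differed between the stages, with Endo (other) at 65% of annotated cells in E9.5 E+HE+IAC and 20.8% in E10.5 E+HE+IAC. A signal also stood in cells the comparisons of types do not use, those without a type, 11938 over all libraries. Of these 1179 came from E11.5 IAC replicate 1, with pan-endothelial genes at 6454 plain CPM in sum, pan-hematopoietic genes at 453 and Runx1 at 0.888.

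The first pattern is the joint fall of S phase, G2M, MYC and ribosomal protein genes from Endo to Conflux endo, in 104 of 105 tested members with a median log2 fold change of -1.19. With counts thinned to 1 total per library 99 of 102 fell (median -0.984), so the calls did not need the larger totals of Endo. Thinning a sum by one factor leaves expected folds and the depth per cell as they were. In E10.5 E+HE+IAC 261 Conflux endo cells held 2447126 UMIs and 2683 Endo cells 37235352. Whether depth per cell plays a part therefore stays open. With Endo restricted to the types marked [AE], 85 of 105 still fell, but the median shrank from -1.19 to -0.552. A mix of endothelial types in the Endo sums may therefore carry part of the fall, and how much stays open. It stays open how far cells were placed in Conflux endo because they cycled less, since the authors drew the types from the same values and all 104 could follow from that. Slower division and growth on the way into the transition may explain it too, and the series holds no other measure of cycling.

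The second pattern is the lack of any gene past the threshold between the HE and E gates at E9.5 over all cells in edgeR without a block, where DESeq2 called 138. Cells of other types in the sorted libraries could hide the difference, and 133 genes passed with annotated endothelial and EHT cells only, all cells of other types being left out. The 2 sort gates cannot be told apart from the replicate numbers. With the replicate number as a block 105 genes passed, 97 up and 8 down. That could mark the gates or chance between 2 pairs of libraries.

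The third pattern is the lower share of HE and IAC cells in the Runx1+/- libraries. Other cells in the denominator were argued against: among Conflux endo, Pre-HE, HE and IAC cells alone the share was 28.8 ± 2.93% in Runx1+/+ and 7.26 ± 3.12% in Runx1+/- (SD, n = 2 each), with within-replicate ratios of 0.189 and 0.306. Pre-HE cells took 37.7 ± 4.45% and 57.3 ± 6.81% of these, a share that rises by itself when HE and IAC take less. Beside Conflux endo alone, Pre-HE had 29 against 23 cells and 38 against 38 in Runx1+/+ replicates 1 and 2. In Runx1+/- it had 52 against 42 and 92 against 42. Chance between libraries stays open, as an exact permutation p of 0.333 is the smallest possible for 2 against 2. A block at the passage from Pre-HE to HE under a lower Runx1 dose would also give this pattern, and more libraries would be needed to tell.

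Splits of the same libraries were set beside the real groupings. The types were drawn from the same values, so the real grouping of types was bound to rank high, and these splits say only that a random grouping of the sums does not give as many genes. Of 100 splits, only 1, the real one, had as many genes past the threshold for Conflux endo against Endo (4304, highest other 2713), Pre-HE against Conflux endo (1406, highest other 811), HE against Pre-HE with sorted libraries (1959, highest other 1437) and IAC against HE with sorted libraries (3664, highest other 2166). It was also 1 of 100 for Wnt_high against Wnt_low endothelium (3326, highest other 0) and for annotated Endo cells between stages (1661, highest other 288), and 1 of 35 for annotated HE against Endo cells at E9.5 (1780, highest other 939).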

How the results depend on the processing

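Of the counts and values compared under other settings, 208 kept their call or stayed near their value, 91 moved and 6 reversed. Of the values of single genes, 2300 kept direction and side of the threshold, 161 became weaker, 11 became stronger and 11 reversed. Among the genes named as largest rises or falls, counted once per comparison, 191 of 191 kept their direction and 121 stayed past the threshold under every setting run. For HE against Pre-HE and IAC against HE these settings could not leave out E10.5 E+HE+IAC, the only library with HE there. The 11 reversals of single genes were all of Runx1. The 6 reversed values were shares of Conflux endo and Pre-HE cells and the Runx1 ratio of LMPP against HSC. The settings in the added fits were chosen after the data were seen. The cR1 Cre- library could not enter the steps, and no alternative was run for it there. With 6 residual degrees of freedom and 1 library in most sorted groups, the simulated test recovered 2% to 8% of 2-fold changes over all cells, apart from 0% for the interaction, so whole-library counts near 0 set no limit on such changes. Depth limits genes of a few CPM in small types: HE of the steps had 1288641 UMIs.

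Whole libraries, genes past the threshold. For HE against E at E9.5 (0 in edgeR) there were 30 without a filter, 138 with DESeq2, 2 with limma, 133 with annotated endothelial and EHT cells only, 101 without Endo (low quality) too, and 1780 in one model of annotated cells. For E10.5 E against E9.5 E (0) the values were 2 without a filter, 6 with DESeq2, 6 without Endo (low quality) and 1661 in one model. For HE against E at E10.5 (200) they were 161 with RLE, 1031 without a filter, 1785 with DESeq2, 1509 with only the compared groups, 7 with limma, 1780 with endothelial and EHT cells, 1735 without Endo (low quality) and 2685 in one model. For the interaction (0) they were 28, 371, 26, 209 and 148 (no filter, DESeq2, endothelial and EHT cells, without Endo (low quality), one model). For E11.5 against E10.5 IAC (0) DESeq2 gave 166, limma 7, sums without Endo (low quality) 50 and annotated IAC cells 788. For CD45+CD27+ IAC (0) they were 164 without a filter, 331 with DESeq2, 51 with limma, 23 with endothelial and EHT cells and 25 without Endo (low quality). For Runx1+/- (0) DESeq2 gave 3. RLE factors shifted the median log2 fold change by -0.143 for HE against E at E10.5 and by -0.163 for the interaction. The cause of these moves was not tested.

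With 1 library left out, HE against E at E9.5 gave 0 to 4 genes (4 without HE replicate 1), E10.5 against E9.5 E 0 to 1, HE against E at E10.5 0 (without E replicate 2) to 6 (without E replicate 1), the interaction 0 to 5 (5 without E9.5 HE replicate 2), IAC between stages 0 to 108, CD45+CD27+ IAC 0 to 440 (both without E11.5 IAC replicate 2) and Runx1+/- 0. Counting sums without Endo (low quality) among these, the upper ends were 101, 6, 1735, 209, 108 and 440. A lone library left in a group is assumed to vary like the other groups.

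No label says that libraries with the same number share a litter or day, and for E9.5 HE and E the number goes with the gate. With a replicate block 105 genes passed for HE against E at E9.5, 0 for E10.5 E against E9.5 E and 0 for Runx1+/- over all cells, where deviations of same-numbered libraries had correlations of 0.26, -0.21 and 0.45. With crossed numbers 217 passed for E10.5 E against E9.5 E. Within types the replicate block gave 90 for Runx1+/-, 50 of them in Endo (Wnt_high) and 25 in contaminating cells. Every block fit used the compared libraries alone and spent a residual degree of freedom on the block.

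For the steps, Conflux endo against Endo (4304) gave 2293 with 50 cells per type, 2529 with thinned counts, 2123 with [AE] types and 2620 to 4282 with 1 library left out. RLE gave 2180 up and 2045 down there. Pre-HE against Conflux endo (1406) gave 544 with 50 cells and 807 to 1316 with 1 left out. Both lowest values came without the E10.5 E+HE+IAC library. HE against Pre-HE gave 1959 and IAC against HE 3664 with sorted libraries added, E9.5 libraries among them. The E10.5 E+HE+IAC library, the only source of HE in the main fits of these steps, could not be left out. Runx1+/- within 7 types (0) gave 77 without a filter, 4 with DESeq2 and 0 in one model, and 72 to 191 with 1 library left out. With at least 50 cells it gave 0 in Endo (other), Endo (Wnt_high), Endo (Wnt_low) and contaminating cells. Conflux endo, Endo (low quality) and Pre-HE were not fitted at that minimum.

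In the added fits with 1 library left out, HE against Endo gave 555 (without E9.5 HE replicate 2) to 1552 at E9.5 and 763 (without E10.5 HE) to 2768 at E10.5, Endo between stages 1060 to 1915, HE between stages 0 to 363, the interaction 1 to 249, IAC cells 4 to 1153 and Wnt_high against Wnt_low 2658 to 3049. DESeq2 gave 295 for HE between stages, 223 for the interaction and 1792 for Wnt_high.

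Shares of Runx1+/- less Runx1+/+, in percentage points with 1 library left out, ran from -0.805 to -0.0458 for HE, -1.01 to -0.973 for IAC, -1.81 to -1.02 for HE with IAC, -1.03 to 1.29 for Conflux endo and -0.0937 to 1.76 for Pre-HE. Conflux endo reversed with the EHT denominator (-0.256) and without Runx1+/+ replicate 2 or Runx1+/- replicate 1 (-0.415, -1.03), and Pre-HE without the same libraries (-0.0596, -0.0937). The cause was not tested.

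Runx1 reversed, without passing, for E10.5 against E9.5 E (log2 -0.509 and -0.242 with endothelial and EHT cells, -0.111 without E9.5 E replicate 1, -0.165 without E10.5 E replicate 2, range to 0.538), the interaction (HE minus E at E10.5 minus the same at E9.5: Runx1 log2 fold -0.271 to 2.01, lowest without E9.5 HE replicate 1), Conflux endo with [AE] types (0.102), IAC against HE (-0.075 thinned, -0.0243 with sorted libraries), annotated Endo at E10.5 vs E9.5 (-0.598 to 0.01) and the stages of IAC (IAC cells: E11.5 vs E10.5 libraries: Runx1 log2 fold 0.0516 without E10.5 IAC, 0.191 without E11.5 CD45+CD27+IAC, lowest -0.349). The cause was not tested. For IAC against HE the main Runx1 log2 fold change was positive, although its mean CPM was lower in IAC. Of 1 against 1, LMPP against HSC reversed under TMM (0.30) and CD45+ IAC moved to -0.21 with TMM and -0.22 within IAC. The arteries against the aorta gave 2.18 within Endo (other) and 4.48 within contaminating cells, with 6, 3 and 8 lists outside the central 95% of random lists within Conflux endo, Endo (low quality) and Pre-HE.

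Gene lists called past the threshold by camera with the preset correlation went from 109 to 0 with an estimated correlation and 15 with fry over whole libraries, from 59 to 24 with an estimated correlation in the 4 steps (60 with fry), from 30 to 0 and 0 for Runx1+/- within types, and from 92 to 15 with an estimated correlation in the added fits (70 with fry).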

Other observations

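Endothelium of the E10.5 arteries held types that the authors named by Wnt activity. Endo (Wnt_high) cells made up 22.8% of annotated cells in the dorsal aorta library (20.9 to 24.7) and 0.434% in the vitelline and umbilical library. Against Endo (Wnt_low) cells of the same 5 libraries, the Wnt feedback inhibitor gene Nkd1 rose from 4.93 to 100 CPM, the forkhead genes Foxq1 from 0.767 to 57.2 CPM and Foxf2 by a log2 fold change of 6.17, and the retinol receptor gene Stra6 from 0.569 to 42.7 CPM. Htra3 and the secreted Igfbp7 rose by log2 fold changes of 5.26 and 5.11, and the carbonic anhydrase gene Car2 from 8.21 to 164 CPM. The prostaglandin-degrading enzyme gene Hpgd and the potassium channel subunit gene Kcne3 fell, with log2 fold changes of -3.00 and -2.36. Tfrc, which imports iron, rose by 2.39, and with Car2 made 4 of 9 erythroid list members rise (adjusted p = 0.0297 with an estimated correlation). MYC and ribosome biogenesis genes fell in 22 of 24 cases, S phase genes in 20 of 26, 23 adjusted over the list alone, and ribosomal protein genes in 29 of 29 by a median of -0.11 (adjusted p = 0.352, 0.308 and 0.381 with an estimated correlation). In all 3326 of 10877 genes changed in edgeR, 1487 up and 1839 down. The types were drawn by the authors from the same values, and the comparison was added after the data were seen.

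Cells without a type differed between libraries. They made up 27.3% of E10.5 IAC cells (25.5 to 29.2), with Runx1 at 8.79 plain CPM, and 30.1% of CD45+ IAC cells, with Runx1 at 1.91. In E9.5 E replicate 2 they made up 32.8% and had a median of 3421 UMIs, against 12216 in cells with a type. In E10.5 E+HE+IAC they made up 14.9%, with medians of 3146 and 11805 UMIs. Cells without a type in E11.5 IAC replicate 1 had a median of 21481 UMIs. Yolk sac EMP of E9.5 had Runx1 at 194 plain CPM, the highest of the 26 libraries.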
